A study of Mus musculus with 2 samples.

How the data were processed

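Ribosome-bound RNA from the cerebral cortex of mice of the Gdnf-EGFP/Rpl10a line (ES2243) was profiled by translating ribosome affinity purification (TRAP) and RNA sequencing. In this method a ribosomal protein fused to enhanced green fluorescent protein is expressed under the regulatory sequences of a chosen gene, here Gdnf. Tagged polysomes are then pulled from a tissue homogenate with anti-EGFP antibodies, and the RNA bound to them is sequenced. The labels' protocols describe dissection and homogenization of the cortex, immunopurification on antibody-coated magnetic beads and clean-up of the RNA with a small-sample kit. The series design text calls the mice adult and the profiled cells pericytes. The 2 libraries, IP1 and IP2, were both immunopurified samples of this line and formed 1 group. The labels do not say whether they came from different animals or from pools. The spread between them may therefore be technical. Unpurified cortex RNA was not analysed here, so levels are reported and not enrichments over the tissue.

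Per the submitters' processing notes, reads were aligned with STAR version 2.0.0e to the mm10 mouse genome and counted with HTSeq. The gene annotation and the strand setting are not given in the sources used here. Each deposited file holds 1 raw count per gene symbol for 1 library, with no header line and no normalization. It ends with summary lines for reads outside genes, reads matching several genes and reads aligned to several places. These lines, and a row named unknown that held 1 read in IP1 and 0 in IP2, were left out of library sizes and tests. Reads in genes made up 58.1% of all listed reads in IP1 and 57.7% in IP2. Reads aligned to several places were not assigned to genes. Genes with near-identical copies, such as ribosomal protein genes with many pseudogenes, are therefore undercounted to an unknown degree. Without a known strand setting, reads from overlapping antisense genes cannot be told apart.

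The counted reads totalled 65200231 in IP1 and 72732502 in IP2. A gene with no count could have had up to 3 counts, which is 0.046 CPM in IP1 and 0.041 CPM in IP2. This limit does not cover genes that overlap another gene, such as Tsix, Trex1, Gfra3, Il6 and Il1b, since reads matching several genes were not assigned. These limits, and all binomial intervals given, cover counting error only. PCR copies were not marked by molecular identifiers in the files, so reads are not independent molecules.

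Counts were scaled by the total of all gene counts of the library to the usual CPM scale. No gene length was used, so CPM values compare a gene between libraries and rank genes only roughly within one. Values are given as mean ± SD over 2 libraries, or per library. The plan for the tests, the gene lists and the named genes was fixed before the data were examined. It comprised 15 cell type marker lists and 17 functional lists of symbols, plus 2 lists drawn by symbol pattern for cytosolic ribosomal proteins and the nuclear-encoded respiratory chain. Of the listed genes, 1 (Hba-a1) had no row in the files, and 38 genes stood in more than 1 list. For each list the median CPM per library was taken, with the number of members at or above 10 CPM in both libraries. The median was also placed among the medians of 10000 random lists of the same size, drawn from the 19580 genes with at least 1 count. Genes of a list are not replicates, so no p-value was computed for a list. The genes named were Gdnf, Rpl10a, all pericyte and pan-mural markers, and the 4 highest members and up to 4 members without counts of each other list. The 10 most abundant genes, the 6 genes with the largest ratio in each direction among called genes with a mean of at least 10 CPM, Xist and the Y-linked genes completed the rule. Some genes that the rule names are not reported here. Cldn5, Pecam1, C1qa, Slc17a7, Enpep, Ret, Artn, Nrtn, Col4a1 and Lamc1 were added after their values were seen.

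The 2 libraries were compared gene by gene with a two-sided exact binomial test of the reads, given TMM-scaled library sizes from edgeR 4.0.16. The test covered 17306 genes with 10 or more counts in total, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a ratio of at least 2. This test compares the reads of 2 libraries and holds counting error alone. The spread between the libraries was estimated as the common biological coefficient of variation in edgeR with an intercept-only design. Ratios are given as log2 of IP2 over IP1 with a prior of 0.5 counts. The shift of each list was its median log2 ratio, set against 10000 random lists matched on mean expression in 20 bins. An edgeR exact test with an assumed coefficient of variation of 0.1 or 0.2 was run as an alternative, since 2 libraries of 1 group leave no other estimate of error for a ratio. Computation used R 4.3.3, DESeq2 1.42.0 for alternative size factors, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

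The procedures were tested on simulated data built from the real gene means. With counting error only, the binomial test was judged at the adjusted p alone, without the ratio limit used for calls. It recovered 50 of 50 genes changed 1.5-fold and 50 of 50 changed 2-fold among 17310 tested, and it marked 11 unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery at lower levels was not measured. A simulated coefficient of variation of 0.2 was estimated as 0.2 over 13938 genes. With the spread estimated from the libraries and no gene changed, the test still called 1198 of 17277 genes at a ratio of at least 2. At a mean of at least 10 CPM it called 588 of 9656 genes with that single spread of 0.257, and 74 with the spread of 0.178 estimated for those genes. Positions were taken from a RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes, in which 24143 of 32531 symbols were matched. It gives the span of each gene and no exon lengths. The planned length correction was therefore not run, and the planned total without mitochondrial genes did not apply, since 0 symbols start with mt-. Alternatives for scaling, filters, thresholds and left-out libraries are described in the closing section.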

Results

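RNA immunopurified with tagged ribosomes from the adult mouse cerebral cortex was measured in 2 libraries of a line in which a tagged ribosomal protein follows Gdnf, the gene of a neurotrophic factor. IP1 held 65200231 and IP2 72732502 reads counted in genes. Of 32531 genes listed, 13446 reached 1 CPM in both libraries and 9207 reached 10 CPM. The series aims at the transcriptome of cortical pericytes, the contractile cells that wrap capillaries. It has a single group, so the comparisons below are between genes within the libraries and between the 2 libraries.

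The driver gene and the tag gene were both counted at low levels. Gdnf (chromosome 15, 7810048 to 7837580, mm10) was at 9.00 ± 1.65 CPM (SD, n = 2), from 663 counts in IP1 and 570 in IP2. This put it at rank 9947 by mean CPM. Rpl10a (chromosome 17, 28328471 to 28331033), the ribosomal protein that carries the tag, was at 4.06 ± 0.45 CPM (SD, n = 2). It ranked 51 of 76 cytosolic ribosomal protein genes, whose median was 9.96 CPM. Reads aligned to several places were not assigned, which undercounts such genes to an unknown degree. The rank therefore does not give the level of the tag gene relative to the others. Of the other GDNF family genes, the receptors Gfra2 (97.2 ± 3.38 CPM) and Gfra1 (56.7 ± 18.4 CPM) were higher than the ligand, as was Ncam1 (144 ± 51.3 CPM), an adhesion molecule that also binds GDNF. Gfra4 was at 16.7 ± 0.92 CPM. Ret, the signalling receptor, was at 0.61 CPM in IP1 and 4.77 CPM in IP2. The ligands Artn and Nrtn were under 1 CPM in both libraries, and Gfra3 had no count. The median of this list of 10 genes was 5.39 CPM in IP1 and 6.30 CPM in IP2.

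Transcripts of marker genes of mural cells, which are pericytes and vascular smooth muscle, were among the abundant messages. Rgs5 (chromosome 1, 169655501 to 169695813), a regulator of G protein signalling and a widely used mural marker, was the 4th most abundant gene of the table at 4451 ± 551 CPM (SD, n = 2). All 14 genes of the pericyte list and all 14 of the pan-mural list reached 10 CPM in both libraries. The pericyte list had a median of 68.0 CPM in IP1 and 76.6 CPM in IP2, and the pan-mural list 142 CPM in both. Medians this high were exceeded by few random gene lists (percentiles 99.9 and 100 on the mean of both libraries). The same held for lists of other cells, with percentiles of 100 for oligodendrocyte precursor and pan-neuronal markers, 99.98 for oligodendrocyte, 99.97 for astrocyte and 99.8 for excitatory neuron markers.

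Within the pericyte list, Vtn, which encodes the matrix protein vitronectin, led with 491 ± 134 CPM. Abcc9 (451 ± 171 CPM) and Kcnj8 (252 ± 70.3 CPM), the sulfonylurea receptor and pore of a vascular ATP-sensitive potassium channel, lie next to each other on chromosome 6 (142587862 to 142702766 and 142564837 to 142571614). Higd1b (202 ± 54.3 CPM), Atp13a5 (175 ± 48.3 CPM), Gper1 (88.4 ± 11.1 CPM) and the aminopeptidase gene Anpep (87.4 ± 27.7 CPM) followed. Art3 (66.0 ± 9.43 CPM), Ndufa4l2 (60.1 ± 11.3 CPM), Cox4i2 (58.7 ± 12.1 CPM), Slc6a20a (52.3 ± 4.98 CPM), P2ry14 (46.4 ± 2.74 CPM) and Slc19a1 (37.6 ± 0.30 CPM) were lower. Higd1b, Ndufa4l2, Cox4i2, Art3, P2ry14, Gper1, Abcc9 and Atp13a5 overlap another annotated gene, which leaves part of their reads uncertain.

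Of the pan-mural genes, Rgs4 (1849 ± 116 CPM) and the Notch target Heyl (743 ± 249.8 CPM) came after Rgs5. Gucy1b3 (346 ± 59.2 CPM) and Gucy1a3 (335 ± 70.3 CPM), the subunits of the nitric oxide receptor, and Pde5a (206 ± 17.0 CPM), which degrades cyclic GMP, were next. The transcription factor genes Tbx18 (147 ± 31.3 CPM), Foxf2 (99.8 ± 18.8 CPM) and Tbx2 (38.4 ± 7.02 CPM) were all present. Among receptors and surface proteins, Pdgfrb was at 127 ± 17.1 CPM, S1pr3 at 121 ± 11.5 CPM, Cspg4 at 107 ± 46.5 CPM, Notch3 at 102 ± 59.4 CPM and Mcam at 41.9 ± 15.999 CPM. Contractile genes of arterial smooth muscle were also found, with Myl9 at 855 ± 128 CPM, Mylk at 484 ± 35.9 CPM, Acta2 at 339.8 ± 47.7 CPM and Myh11 at 206 ± 0.29 CPM. That list of 16 had a median of 35.4 CPM in IP1 and 30.9 CPM in IP2, and 13 members reached 10 CPM in both. Pan-neuronal and oligodendrocyte precursor markers had higher medians than the pan-mural and arterial lists. The counts given here therefore cannot be credited to mural cells alone.

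Transcripts of endothelial cells, the direct neighbours of pericytes, were scarce. The median of 18 endothelial markers was 1.80 CPM in IP1 and 1.75 CPM in IP2, which was 37.7-fold and 43.9-fold below the pericyte list. The difference was far larger than that between the 2 libraries. Only Emcn (37.7 ± 6.23 CPM) and Slc2a1 (19.7 ± 6.23 CPM) reached 10 CPM in both, followed by Esam (12.5 ± 4.17 CPM) and Flt1 (10.96 ± 1.51 CPM). Cldn5, the tight junction gene of the blood-brain barrier, had 5 counts in IP1 (0.077 CPM) and 0 in IP2, and Pecam1 was at 0.18 and 0.49 CPM. In both libraries, 25 of the 28 pericyte and pan-mural genes were above the highest endothelial marker. Microglial markers were also low, with a list median of 2.39 CPM in IP1 and 2.01 CPM in IP2 and 0 of 14 members at 10 CPM in both. Tmem119 (11.5 ± 2.90 CPM), P2ry12 (6.19 ± 0.66 CPM) and Csf1r (3.69 ± 1.253 CPM) were among the highest of these, and C1qa was at 0.061 and 0.22 CPM.

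Perivascular macrophage markers (list medians 0.36 and 0.77 CPM in IP1 and IP2), ependymal and choroid plexus markers (0.44 and 0.84 CPM) and erythroid genes (0.56 and 0.30 CPM) were lower still. Lyve1, Mrc1, Cbr2 and Cd163 of the macrophage list all had means near 1 CPM. Kl (22.2 ± 4.02 CPM) and Rarres2 (12.5 ± 1.41 CPM) were the highest choroid plexus genes, ahead of Clic6 (3.54 ± 0.91 CPM) and Foxj1 (1.86 ± 0.90 CPM), and Kcne2 had no count. The globin gene Hbb-bs was at 1.35 ± 0.80 CPM, with Hba-a2, Hbb-b2 and Alas2 below it. Genes of perivascular fibroblasts were nearer to the mural ones, with list medians of 41.5 CPM in IP1 and 54.0 CPM in IP2. The highest were Apod (2079 ± 519 CPM), Igf2 (982 ± 213 CPM), Dcn (221 ± 21.4 CPM) and Mgp (74.7 ± 6.03 CPM).

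**Figure D1:**
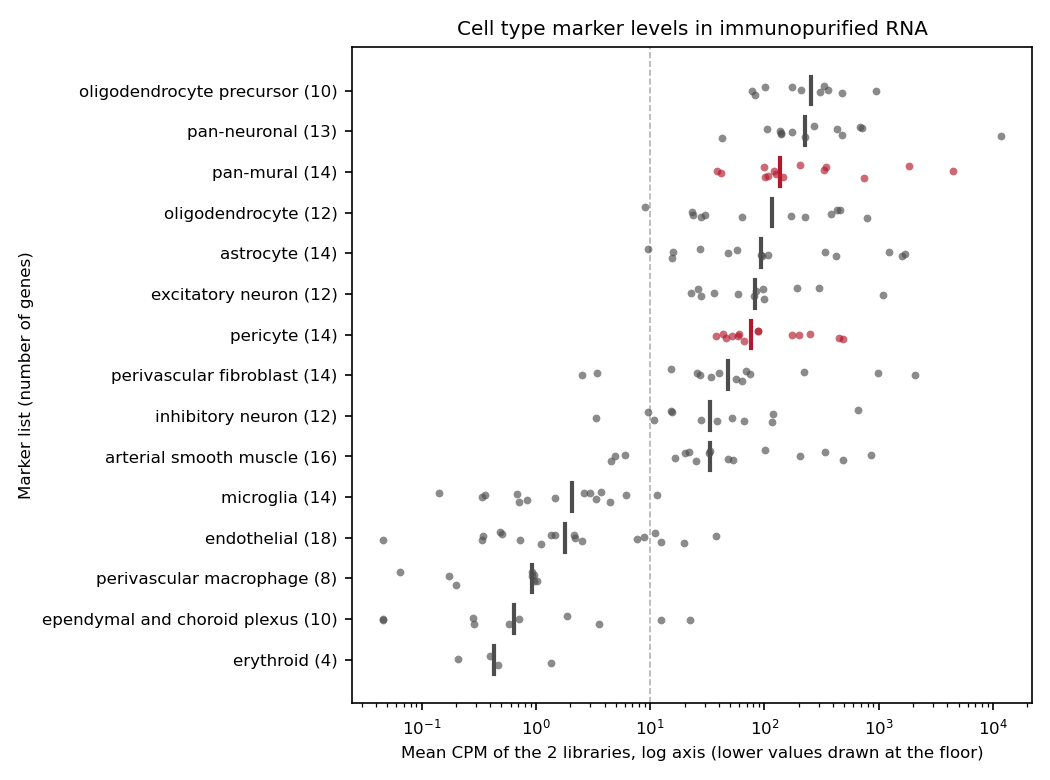
Mean CPM of the 2 libraries on a log axis for each gene of the 15 cell type lists; each point is a gene, vertical bars are list medians, the dashed line marks 10 CPM, lower values are drawn at the 0.046 CPM floor, and the pericyte and pan-mural lists are in red. Endothelial and microglial markers lie mostly below 10 CPM, while all 28 pericyte and pan-mural genes lie above it.

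Lists of neurons, astrocytes and the oligodendrocyte lineage had medians above that of the pericyte list in both libraries, except the inhibitory neuron list, which was lower. All members of the oligodendrocyte precursor, pan-neuronal and excitatory neuron lists reached 10 CPM in both libraries. So did 11 of 14 astrocyte, 11 of 12 oligodendrocyte and 9 of 12 inhibitory neuron markers. On the mean of both libraries, the highest median of the cell type lists was that of oligodendrocyte precursors (186 CPM in IP1, 276 CPM in IP2), with the transcription factor genes Olig1 (949 ± 50.8 CPM), Sox10 (359.9 ± 10.7 CPM) and Olig2 (332 ± 17.3 CPM) and the receptor gene Pdgfra (479 ± 217 CPM). The other members of that list were lower, from 78.1 ± 18.1 to 305 ± 173 CPM. Pan-neuronal markers had medians of 226 and 223 CPM and were the highest list in IP1. Snap25, a synaptic fusion protein gene, was the second most abundant gene at 11783 ± 1396 CPM, and Syt1 (711 ± 16.9 CPM), Syp (691 ± 119 CPM) and Eno2 (476 ± 55.7 CPM) followed. Oligodendrocyte markers had medians of 116 and 119 CPM, with high levels of Cnp (454 ± 32.1 CPM), Mbp (429 ± 44.7 CPM) and Mobp (383 ± 29.6 CPM). Astrocyte markers had medians of 71.5 CPM in IP1 and 114 CPM in IP2, led by Glul (1684 ± 397 CPM), Slc1a2 (1593 ± 615 CPM), Ndrg2 (1242 ± 84.4 CPM) and Aldoc (421 ± 16.1 CPM). Excitatory neuron markers had medians of 81.2 and 84.4 CPM, with Camk2a at 1082 ± 104 CPM, Arpp21 at 301 ± 20.9 CPM, Rorb at 192 ± 24.1 CPM and Nrgn at 98.6 ± 5.68 CPM. The vesicular glutamate transporter gene Slc17a7 was at 94.8 and 101 CPM. Inhibitory neuron markers had medians of 30.6 and 33.1 CPM, with Gad2 at 659.9 ± 29.0 CPM, Gad1 at 119 ± 9.54 CPM, Sst at 117 ± 25.6 CPM and Npy at 66.1 ± 8.83 CPM. In both libraries 6 of the other cell type lists had a higher median than the pericyte list. Marker genes differ in their level in the cells that use them, so these medians do not give shares of cell types.

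The most abundant entry was Rn45s, the ribosomal RNA precursor, with 3.64% of counts in IP1 (exact 95% interval 3.63 to 3.64%) and 3.95% in IP2 (3.946 to 3.955%). After Snap25, the 10 highest included Kalrn (7642 ± 1228 CPM), Rgs5 and the 14-3-3 genes Ywhaz (3980 ± 609 CPM) and Ywhae (3430 ± 166 CPM). Cald1 (2561 ± 192 CPM), Ubr3 (2489.7 ± 219 CPM) and Actb (2480.0 ± 356 CPM) were also among them. The 10 nuclear noncoding RNA genes took 0.121% of counts in IP1 (exact 95% interval 0.121 to 0.122%) and 0.114% in IP2 (0.113 to 0.114%), and their list medians were 6.90 and 6.72 CPM. Malat1 (941 ± 31.7 CPM) and Meg3 (164 ± 20.1 CPM) led, with Snhg11 at 34.01 ± 6.22 CPM, Rian at 19.6 ± 3.83 CPM and no count for Tsix. The 3 globin genes took 0.000304% of counts in IP1 (0.000263 to 0.000349%) and 0.000139% in IP2 (0.000113 to 0.000169%). Xist was at 1.69 ± 0.05 CPM, while the Y-linked genes Ddx3y (46.1 ± 6.08 CPM), Kdm5d (21.3 ± 3.85 CPM), Eif2s3y (18.2 ± 2.04 CPM) and Uty (13.1 ± 6.28 CPM) were all higher, with list medians of 20.8 and 19.1 CPM. The span of Xist lies within that of Tsix, so its reads may have been left unassigned as matching several genes.

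Functional lists described the counted RNA further, and their names do not say which cells the counts came from. Nitric oxide and cyclic GMP signalling was the highest of these in median level (210 CPM in IP1, 168 CPM in IP2, 8 of 11 genes at 10 CPM), with Pde1a at 595 ± 65.4 CPM and the kinase gene Prkg1 at 218 ± 18.9 CPM beside the guanylate cyclase subunits. Mural transcription factors had medians of 162 and 155 CPM, with 13 of 14 genes at 10 CPM. They included Epas1 (1175 ± 34.9 CPM), Mef2c (996 ± 88.2 CPM) and Zic1 (413 ± 35.6 CPM) besides Heyl. Ion channels of contractile vascular cells (medians 39.3 and 39.3 CPM, 19 of 25 genes) held Itpr1 (343 ± 64.5 CPM) and Kcnma1 (104 ± 11.1 CPM) beside the potassium channel pair. Of the vasoactive receptors (6.86 and 9.36 CPM, 11 of 26 genes), Ednrb (127 ± 69.1 CPM), S1pr3, Calcrl (94.1 ± 9.03 CPM) and Ednra (92.2 ± 24.7 CPM) were highest. Cell-surface enzymes (25.2 and 15.6 CPM, 9 of 15 genes) were led by Ece1 (188 ± 61.7 CPM) and Enpp2 (179 ± 46.7 CPM), with Anpep and Art3 next. Enpep (33.0 and 59.6 CPM), a peptidase gene of the angiotensin system, was also detected.

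Basement membrane and matrix genes (18.8 CPM in IP1, 36.5 CPM in IP2, 15 of 22 genes) were led by Vtn, Sparc (465 ± 173 CPM), Timp3 (427 ± 130.5 CPM) and Bgn (376 ± 81.3 CPM). Among growth factors and angiogenic ligands (12.5 and 14.02 CPM, 16 of 30 genes), Ptn, the pleiotrophin gene, was at 2281 ± 641 CPM, with Igf2, Fgf1 (142 ± 46.2 CPM) and Cxcl12 (103 ± 2.21 CPM) after it. Mural-endothelial signalling genes (32.3 and 42.9 CPM, 16 of 23 genes) included Hey1 (168 ± 38.2 CPM) with Heyl, Pdgfrb and Notch3. Membrane transporters (27.3 and 37.5 CPM, 18 of 24 genes) had high levels of Slc7a11 (317 ± 43.5 CPM), Slc22a8 (175 ± 24.2 CPM) and Slc38a2 (173 ± 73.5 CPM). Genes linked to small vessel disease and brain calcification (47.7 and 49.1 CPM, 15 of 18 genes) were led by Itm2b (383 ± 63.4 CPM), Xpr1 (290.1 ± 33.3 CPM), App (286 ± 58.3 CPM) and Cst3 (228 ± 68.4 CPM), and Trex1 had no count. Hormone and metabolic receptors (51.1 and 44.7 CPM, 10 of 14 genes) were led by Nr3c1 (228 ± 12.1 CPM), Thra (208 ± 15.1 CPM), Thrb (131 ± 4.13 CPM) and Rxra (86.4 ± 3.38 CPM).

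Of the chemokines, cytokines and innate immunity genes (10.7 and 8.28 CPM, 15 of 31 genes), Ifitm3 (208 ± 10.7 CPM), B2m (185 ± 38.9 CPM), Ifitm2 (158 ± 7.59 CPM) and Il33 (112 ± 30.7 CPM) were highest. The inflammatory cytokine genes Il6, Il1b and Tnf had no count. Hypoxia and glycolysis genes (28.8 and 24.1 CPM, 11 of 15 genes) were led by Aldoa (625 ± 105 CPM) and Ldha (297 ± 31.0 CPM), with Ndufa4l2 and Cox4i2 next. The nuclear-encoded respiratory chain (46.6 and 37.7 CPM, 73 of 88 genes) was led by Atp5b (2214 ± 276 CPM), Atp5a1 (793 ± 39.8 CPM), Atp5c1 (310.4 ± 85.3 CPM) and Atp5g3 (232 ± 15.3 CPM), and Cox8c had no count. Cytosolic ribosomal protein genes (10.8 and 9.52 CPM, 36 of 76 genes) had high levels of Rpl4 (400.3 ± 56.8 CPM), Rps3 (169.8 ± 19.95 CPM) and Rpl8 (85.4 ± 13.6 CPM).

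The 2 libraries ranked genes alike. Across 19580 genes, Pearson's r of log2(CPM + 1) was 0.988 and Spearman's rho 0.977, as a description over genes, which are not independent replicates. Of 9656 genes with a mean of at least 10 CPM, 88.6% differed by no more than 1.5-fold and 98.3% by no more than 2-fold. The libraries differed by more than counting error, with a chi-square of 88.9 per degree of freedom over 17306 genes, so they were not treated as copies of 1 library. This does not show that they came from different animals. Their common coefficient of variation was 0.257 over 13956 genes.

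**Figure D2:**
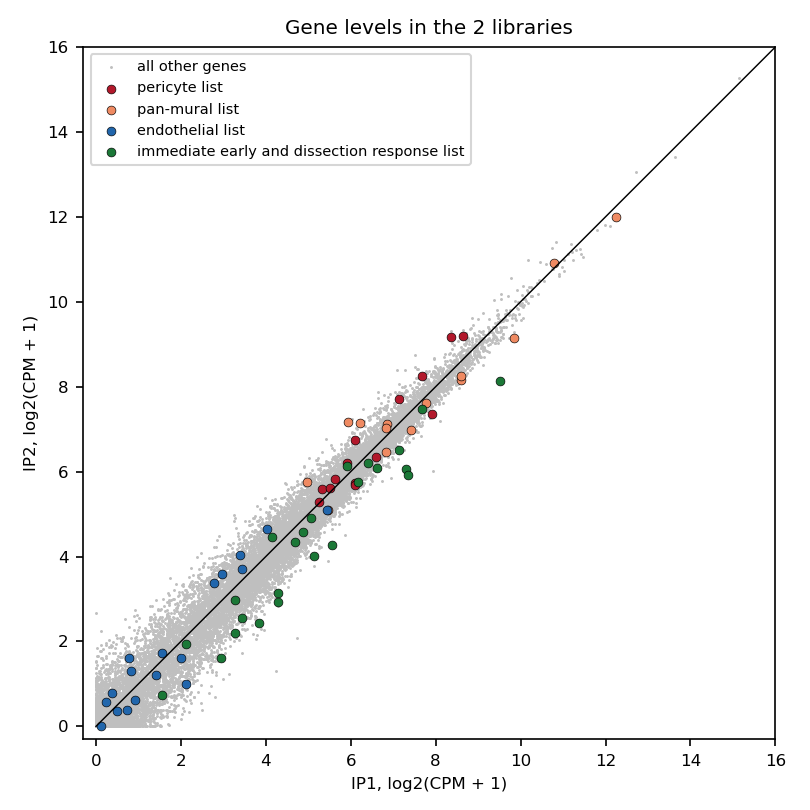
Level of each gene in IP1 (x axis) and IP2 (y axis) as log2(CPM + 1), with the pericyte, pan-mural, endothelial and immediate early lists in colour and the line of equality in black. The genes lie along the line (Pearson's r 0.988), and most immediate early genes lie below it.

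Immediate early genes, which respond to activity and to tissue handling, were higher in IP1. Of 24 such genes, 11 were called higher in IP1 and 0 in IP2 by the exact binomial test with Benjamini-Hochberg adjustment and a ratio of at least 2, and 21 passed the adjusted p alone on the IP1 side (also 21 adjusted over the list alone). That test, which holds counting error only, passed 13068 of all 17306 genes, 6583 on the IP1 side and 6485 on the IP2 side. Egr1 fell from 728 CPM in IP1 to 281 CPM in IP2 and Dusp1 from 158 to 65.8 CPM. Klf6 (202 and 178 CPM) and Zfp36 (140.5 and 89.7 CPM) were the other highest members. The list's median log2 ratio of IP2 over IP1 was -0.78, below the medians of all 10000 matched random lists. The 6 genes with the largest ratio towards IP1 were taken among called genes with a mean of at least 10 CPM. Of these, Nr4a1 (log2 ratio -1.40) and Cyr61 (-1.43) belong to the immediate early list. Apold1, an early response gene of the vasculature outside the list, had a log2 ratio of -1.88. Pttg1, the securin gene, had the largest ratio of the 6 (-2.92), with 25.7 CPM in IP1 and 3.26 CPM in IP2. Rabl3 (-1.57) and Thap6 (-1.55) completed the 6. Some called genes with a lower mean had larger ratios.

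Genes of the basement membrane and matrix were higher in IP2. Their median log2 ratio was 0.83, and 21 of 22 passed the adjusted p on the IP2 side (also 21 adjusted over the list alone), against 6485 of 17306 genes in all. Of the 21, 5 had a ratio of at least 2. Col4a1 rose from 15.2 to 32.1 CPM and Lamc1 from 140.1 to 268 CPM. Cell-surface enzymes (median log2 ratio 0.70), small vessel disease genes (0.60), astrocyte markers (0.58), vasoactive receptors (0.42), perivascular fibroblast markers (0.40), mural-endothelial signalling genes (0.39), membrane transporters (0.35), ion channels (0.33), oligodendrocyte precursor markers (0.29), oligodendrocyte markers (0.29) and pericyte markers (0.28) were also above the central 95% of matched random lists. The cell-surface enzymes differed in sign between measures, since their median level was lower in IP2 while 13 of 15 members passed the adjusted p on the IP2 side. Pan-mural markers (-0.16), the respiratory chain (-0.21) and ribosomal proteins (-0.28) lay below that range, with the immediate early genes. The other 18 of the 34 lists lay within it. At the nominal rate 1.7 of 34 would fall outside, but that rate takes genes and lists as independent. Genes of 1 list can vary together and 38 genes stood in more than 1 list, so the number outside cannot be judged against it. Of the pericyte and pan-mural genes, Notch3 alone was called (59.7 CPM in IP1, 144 CPM in IP2). Ednrb (77.6 and 175 CPM) and Pdgfra (326 and 632 CPM) were called among other listed genes. Pdgfra was no longer called by the edgeR exact test with an assumed coefficient of variation of 0.2. That value is less than the 0.257 estimated over 13956 genes and more than the 0.178 estimated at a mean of at least 10 CPM. The 6 genes with the largest ratio towards IP2 were also taken among called genes with a mean of at least 10 CPM. They included Slc17a8 (log2 ratio 1.89), AI464131 (1.85), the collagen prolyl hydroxylase gene P4ha1 (1.78), Hif3a (1.77) and Srebf1 (1.76). Some called genes with a lower mean had larger ratios.

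**Figure D3:**
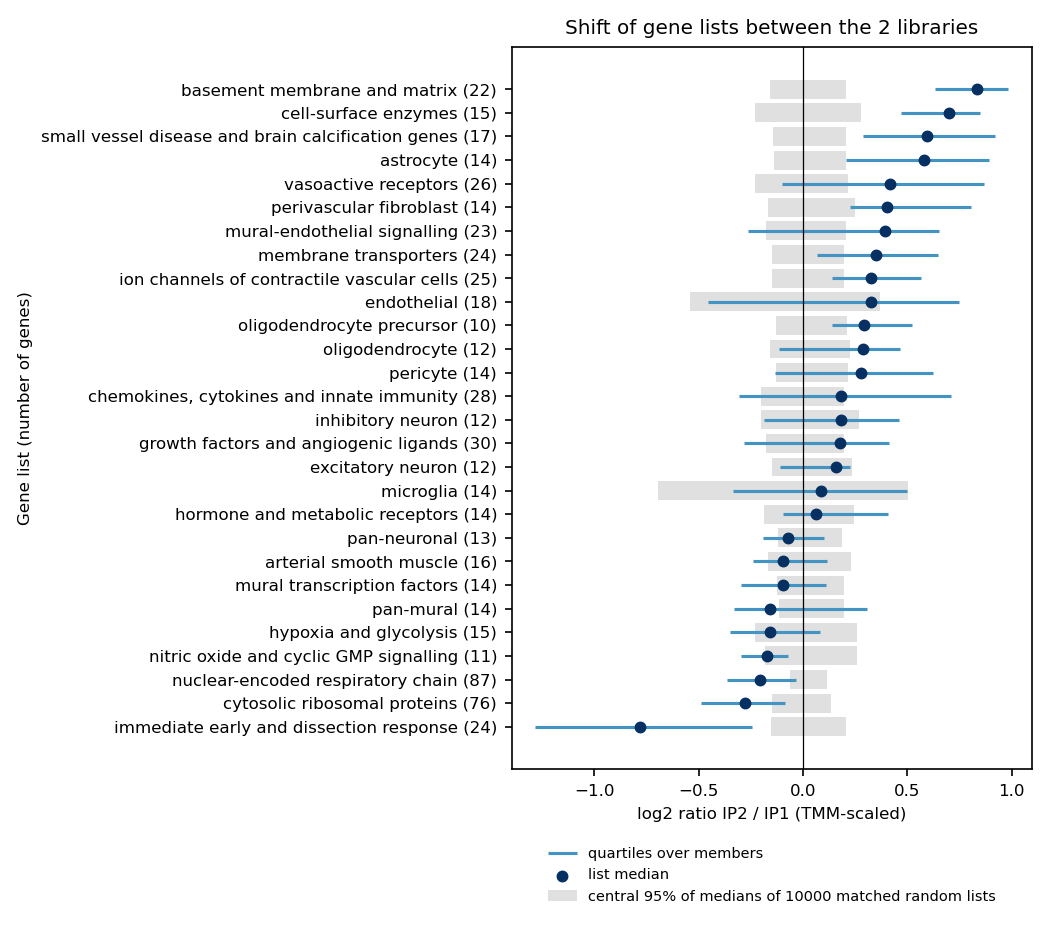
Median log2 ratio of IP2 over IP1 (dots) with quartiles over members (lines) for the lists in which at least 10 genes had a ratio, beside the central 95% of medians of 10000 random lists matched on expression (grey bars). The basement membrane and matrix list (0.83) and the immediate early list (-0.78) lie farthest from 0.

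In all, 3007 of 17306 genes were called between the libraries, 1760 higher in IP1 and 1247 higher in IP2, by the exact binomial test. At a mean of at least 10 CPM there were 162, of which 42 were higher in IP1 and 120 in IP2. Simulated libraries with a single spread of 0.257 for every gene and no changed gene gave 1198 calls. Without a filter on level the estimate was 0.420, so the 1198 do not show how many of the 3007 calls exceed the spread. At a mean of at least 10 CPM the real libraries gave 162 calls. There the simulated ones gave 588 with the spread of 0.257 and 74 with the spread of 0.178 estimated for those genes. The calls compare these 2 libraries and not conditions.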

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

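The files list reads that the per-gene comparisons do not use. They are given here because they are part of the data outside the main measurement. Whether their number is unusual was not tested. Reads aligned to several places made up 31.2% of all listed reads in IP1 and 31.5% in IP2. Reads outside annotated genes made up 9.10% and 9.20%, and reads matching several genes 1.64% and 1.60%. No control library was used to set these values against. With 2 libraries in 1 group, neither unusual samples nor differences of an effect between groups were tested.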

How the results depend on the processing

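The alternatives were planned before the data were examined, except the total without Rn45s and the lists without genes of another cell type list. With genes of another cell type list left out, 2 list shifts moved, by the rule given below, and 10 did not. Under each scaling, the filter on members and either library alone, 10 of 15 cell type lists had a median of at least 10 CPM in both libraries, as in the report. The pan-mural median over both libraries was 136.70 CPM. It was 136.63 with TMM-scaled CPM, 136.51 with DESeq2 size factors, 142 with the total without Rn45s, and 141.739 to 141.740 with either library alone. The pericyte median (76.7 CPM over both) was 68.0 to 76.6 with either library alone. The endothelial median (1.81 CPM over both) was 1.88 without Rn45s, 2.14 without members under 10 counts, and 1.75 to 1.80 with either library alone. At 5 CPM, 6 endothelial and 2 microglial genes reached the threshold, and at 20 CPM, 1 endothelial gene. The microglial median (2.06 CPM) was 2.80 without members under 10 counts and 2.01 to 2.39 with either library alone. Pearson's r was 0.976 with a pseudocount of 0.1. The coefficient of variation was 0.420 without a filter and 0.178 at a mean of at least 10 CPM. The called genes numbered 1783 at 50 or more counts and 13068 with no ratio limit, while edgeR's exact test with an assumed coefficient of variation of 0.2, below the estimated 0.257, kept 2021 of the 3007. Nuclear noncoding RNA took 0.0680% of all listed reads. Over all alternatives, 20 recomputed values, which belong to 10 main results, and 83 recomputed values of single lists and genes moved by more than the spread between the libraries or, for counts, 1.5 times, and none changed the sign of a called value. The causes were not tested. No paired analysis was possible because there is 1 group. The length correction and the total without mt- genes were not run. For genes with no count that overlap no other gene, depth leaves up to 0.046 CPM in IP1.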

Other observations

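The sorting of genes and the tests of explanations in this part were chosen after the results were seen, while the median ratios of whole lists were planned. In some lists the 2 libraries differed by the kind of protein a gene encodes. Members of 8 cell type lists (pericyte, pan-mural, astrocyte, oligodendrocyte, oligodendrocyte precursor, pan-neuronal, excitatory and inhibitory neuron) were sorted by hand after the ratios were seen, from textbook knowledge, into those that encode membrane or secreted proteins and those that encode intracellular ones, with 1 oligodendrocyte precursor gene left unsorted. Of the former, 45 of 48 were higher in IP2, with a median log2 ratio of 0.50, and of the latter 17 of 52, with a median of -0.10. In the pericyte list, 10 of 11 membrane or secreted members were higher in IP2, while Higd1b, Ndufa4l2 and Cox4i2, whose products are mitochondrial, were all higher in IP1. In the astrocyte list the medians were 0.89 for membrane or secreted and 0.17 for intracellular members, and in the oligodendrocyte list 0.41 and -0.10. At least 1 list of mostly secreted products showed a smaller shift towards IP2. The growth factors and angiogenic ligands had a median log2 ratio of 0.18, within the range of matched random lists. Of these 30 genes, 16 passed the adjusted p of the exact binomial test on the IP2 side and 7 on the IP1 side. Over all 17306 genes tested, 6485 passed on the IP2 side and 6583 on the IP1 side. This sorting describes the ratios it was made from, and no explanation of the split was tested.

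Whether the rise of immediate early genes in IP1 went beyond that split depended on the genes compared. The upper quartile of their log2 ratios (-0.24) lay below the median of 216 zinc finger genes (difference -0.21). The products of those genes are intracellular like those of most of the list, though not Cyr61, which is secreted. The quartile lay above the median of the 12 intracellular pericyte and pan-mural members (-0.33), while the list's median (-0.78) lay below it. The split was therefore not excluded. The quartile also lay below the median of all pan-neuronal markers (difference -0.17), a list that holds both kinds of protein. For immediate early genes with a mean of at least 10 CPM the quartile was -0.15. This was just above the median of the intracellular pan-neuronal members (-0.17). The comparison therefore did not decide whether IP1 held a larger share of neuronal RNA. The whole pan-neuronal (-0.07), excitatory (0.16) and inhibitory neuron (0.18) lists had median log2 ratios within the range of matched random lists. A difference in handling or in the state of the animals may remain, and the labels do not record either.

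Neuronal, astrocyte and oligodendrocyte-lineage markers stood beside the mural ones, while most endothelial and microglial markers were low. The endothelial median was 0.0081 of the pan-neuronal one, and the median of oligodendrocyte precursors was 3.36 times that of the pericyte list. Unbound cortical RNA carried through the purification and tagged ribosomes in cells other than mural cells could each bring in neuronal, astrocyte and oligodendrocyte-lineage messages. Carry-over would also bring in endothelial and microglial messages, at the ratio to neuronal ones that unpurified cortex has. That ratio was not measured here, so these explanations cannot be told apart without an unpurified cortex library. The endothelial and microglial lists ranged up to Emcn (37.7 ± 6.23 CPM) and Tmem119 (11.5 ± 2.90 CPM).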
